A study of Arabidopsis thaliana with 12 samples.

How the data were processed

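The material was whole seedlings of Arabidopsis Col-0 wild type and of sfps-2, a knockout of SFPS in the same background, 4 days old and dark grown, sampled after a further 3 h in the dark or in red light of 7 umol m-2 s-1. Libraries were stranded and made from total RNA freed of ribosomal RNA. Each of the 4 groups has 3 libraries, and all 12 were mapped to their group by the labels, with 0 per-sample columns left unmapped.

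Per the labels, reads were checked with FastQC and aligned with TopHat2 to TAIR10. Expression was estimated and tested with Cufflinks, and splicing was counted and tested with ASpli. No versions are stated. The expression tables hold FPKM per group, computed by the authors from the 3 replicates together and scaled between the groups of each table separately. They hold no value per library. The log2 fold changes in the authors' short lists are the log2 ratio of the 2 FPKM values, and in the full tables log2 was computed here from the FPKM. The p-value and q-value columns are the authors' Cuffdiff results, with a floor of 5e-05 on p, so genes at the floor share the lowest q (0.00116, 0.00138, 2.92e-04 and 3.82e-04 in the 4 tables). The test statistic column was used as a score per the file headers. The splicing sheets hold junction read counts per library, as deposited, for the events that passed the authors' FDR of 0.05 and a change of 3 points or more. Events below those thresholds were not analysed here. The fraction columns are the authors' inclusion or retention shares from junction reads summed over a group, and all shares recomputed here matched them within 0.1 points. Sheets without inclusion shares were not used here, nor were the sheets for 10 points, which are a subset of those for 3 points. The gene ontology tables hold numbers of genes, an other unit, as deposited, and were used here only to compare each term with its stated background.

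A gene was called when the authors' q was under 0.05 and the fold at least 1.5, out of the genes the authors tested. A splicing event was called as listed by the authors. Gene lists, tests, thresholds, settings to be varied and the rule for named genes were fixed before the data were examined. The 14 lists hold 269 genes matched by locus code. List members called higher, and apart from these lower, were compared with all other tested genes by two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over lists, directions and comparisons. Members were also adjusted over the list alone. Each list's median change was ranked among 10000 random lists matched on FPKM decile. For splicing, list members with an event were compared with all other genes tested for expression. Genes were not matched for number of introns in these tests or in the overlaps of genes with events. A list of 21 indole defence genes was added after the values were seen.

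Named genes are SFPS, the 6 largest rises and 6 largest falls per comparison among called genes with at least 1 FPKM in both groups, up to 2 list members per direction, the 6 events with the largest change, up to 4 events of the light signalling, clock and splicing regulator lists, and the 6 genes with the smallest p in the comparison of light responses. A rule could be used for fewer genes than it gives, from the top. Other genes were named after their values were seen, as members behind small counts or as examples of a pattern. A result that needs a withheld item is not reported here.

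The light responses of the genotypes were compared by the difference of the log2 fold changes over the root of their summed squared standard errors, two-sided normal p, adjusted over 20420 genes. Each standard error was the log2 change over the Cuffdiff statistic, multiplied by a factor, because the statistic alone gives errors wider than the p-values. The factor was the median, per comparison, of the ratio of that statistic to the normal deviate of its p (0.577 to 0.578). Genes at the p floor, 3533 for light in wild type and 2745 for light in sfps-2, have no exact deviate. For them the factor is an extrapolation. Slopes have bootstrap intervals from 1000 draws over genes. Retention shares were tested by the two-sided exact binomial test with Wilson intervals and between comparisons by Fisher's exact test. Events of a gene are not independent, and intervals cover counting error only. With 3 libraries against 3, no two-sided exact test per event can go below 0.1. Limma was fitted to the log2 odds of inclusion per library, with 0.5 added to each read number, within the listed events, and for genotype by light in 582 bins listed for all 12 libraries.

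Introns were matched by coordinates to RefSeq introns on TAIR10.1, with 96.2% to 97.6% of intron bins matching. Splice sites were scored as the sum of log2 odds of each base against an even composition, over 9 bases at the 5' site and 17 at the 3' site, with frequencies from annotated introns. Means of intron features were compared with 100000 random draws, with replacement, from introns of expressed genes or from introns of the same genes, two-sided, adjusted over 48 tests. A permutation test had been fixed beforehand for this, and drawing with replacement departs from it.

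Whether replicate numbers pair libraries was checked by correlating deviations from group means. They did so in junction reads per gene between the dark groups (r 0.145, 0.151 and 0.150 for replicates 1, 2 and 3 over 900 genes), and not in splicing shares (0.215, -0.0678 and 0.195). The labels name no shared day or batch, and no paired fit of the expression tables was possible. Junction reads per gene, here and below, were summed over listed bins. They were scaled by each library's junction reads in nuclear bins listed for all libraries, so they are not whole numbers.

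Junction reads give the precision of a share, with a median of 265, 249, 207 and 204 reads per event and library in the 4 comparisons. Alternatives tried were other thresholds on fold, q, FDR and change, pseudocounts of 1 and 0.1 FPKM, filters on FPKM, 1 event per gene, 3 strata of FPKM, leaving out each library, a replicate block, other scalings and limma. On simulated data, with 300 genes changed by 2 on the log2 scale, the comparison of light responses called 271 of them and 11 others. Its noise was drawn with the same rescaled standard errors that the test divides by. That simulation therefore checks neither the rescaling nor the effect of differences between libraries. The list test found 1 planted list and 0 of the others, and limma called 78 to 84 of 100 shifted events with 1 to 7 others. Random draws gave a p of 1e-05 for shifted introns and 0.602 for unshifted ones. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.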

Results

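RNA sequencing measured gene expression and splicing in 4-day-old dark-grown Arabidopsis seedlings, in wild type Col-0 and in the sfps-2 mutant of SFPS (AT1G30480), a splicing factor that acts in phytochrome light signalling. Seedlings of each genotype were kept in the dark or given 3 h of red light at 7 umol m-2 s-1, with 3 libraries in each of the 4 groups, 12 in all. The labels do not say whether the 3 replicates were grown as separate cultures. Expression is given as group FPKM from the authors' tables, without values per library, so no error stands beside an expression level. Splicing is given as a retention or inclusion share computed from junction reads per library, with its SD. The total reads per library are unknown. The 133 chloroplast-encoded and 146 mitochondrion-encoded genes are listed at 0 and were not tested. In 581 nuclear intron and exon bins listed for all 12 libraries, junction reads ranged from 288640 to 398115 per library, a ratio of 1.38. Unless named otherwise, a gene was called when its q was under 0.05 and its fold at least 1.5, and list tests are two-sided Fisher's exact tests adjusted over 112 tests, of which 30 passed. These tests take genes as independent, although genes are not independent replicates. Their p-values therefore do not measure the spread between libraries.

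SFPS mRNA was lower in sfps-2 in both light conditions. In the dark it was at 8.04 FPKM in wild type and 1.83 FPKM in sfps-2, a log2 change of -2.14. After red light it was at 7.90 FPKM in wild type and 1.93 FPKM in sfps-2, a log2 change of -2.04. Red light itself left SFPS uncalled in wild type (log2 change -0.01) and in sfps-2 (log2 change 0.08). The mutant also lacked spliced reads over the first intron of SFPS, on TAIR10 chromosome 1 from 10791185 to 10792129, 945 bp long. Wild type had 134, 106 and 106 spliced reads in the dark libraries and 100, 86 and 90 in the red light libraries, whereas all 6 sfps-2 libraries had 0. Reads crossing the 5' boundary of this intron were still seen in sfps-2, 34 over the 6 libraries, with 0 at the 3' boundary. Wild type had 57 reads at the 5' boundary and 34 at the 3' boundary. The 0 spliced of 34 reads in sfps-2 allow a spliced share of up to 8.82%, counting error only. The authors' deposited table lists the intron as retained in 5.08% of wild type and 100% of sfps-2 junction reads in the dark (FDR 8.98e-05), and in 8.91% and 100% after red light (FDR 7.92e-08). Each sfps-2 library contributed between 1 and 11 reads to that share.

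**Figure D1:**
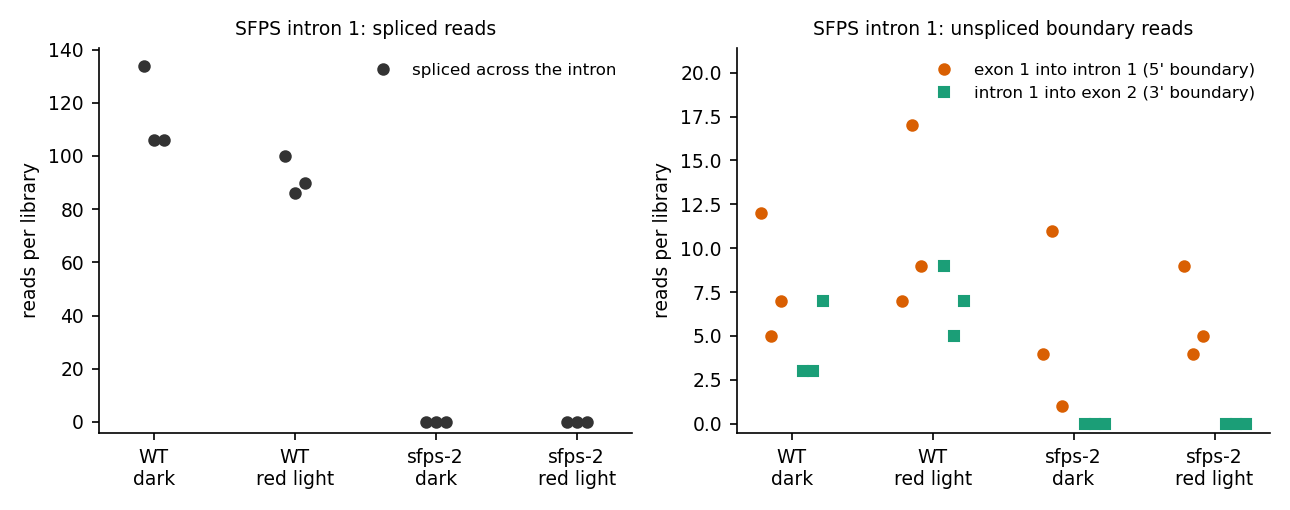
Reads over the first intron of SFPS in each library (read counts on the y axis, libraries by group on the x axis). All 6 sfps-2 libraries had 0 spliced reads and 0 reads at the 3' boundary, against 86 to 134 spliced reads per wild type library.

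The first comparison asks what loss of SFPS does in dark-grown seedlings. In the dark, sfps-2 seedlings held more mRNA of most listed seed storage genes and of part of the photosynthesis and chlorophyll genes than wild type, and less of several auxin and clock genes. SFPS itself was among the 6 largest falls. SESA5, a seed storage albumin, rose from 6.57 to 168 FPKM (log2 change 4.67). Among called genes with at least 1 FPKM in both groups, the largest rises were in the cytochrome P450 gene CYP71A12 (from 1.46 to 82.7 FPKM, log2 change 5.82), the oxidoreductase gene AT1G26380 (5.66), the methyltransferase gene PXMT1 (7.44 to 201 FPKM, 4.75), the coumarin pathway gene AT3G13610 (4.68), SESA5, and the glutathione transferase gene GSTF6 (37.1 to 783 FPKM, 4.40). MRD1 fell from 53.1 to 4.29 FPKM (log2 change -3.63), the light-harvesting gene LHCB1.4 from 31.9 to 2.85 FPKM (-3.49), and the noncoding RNA genes AT1G67105 and AT5G38005 by -2.80 and -2.26. HEI10, a meiotic crossover gene whose locus overlaps that of MRD1, changed by -2.11 in the dark.

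Of 20698 genes tested in the dark, 1080 were called higher in sfps-2 and 411 lower, so 72.4% of the 1491 calls were rises. The authors' short list held 1494 genes, 1478 of them shared. In the list of seed storage and dormancy genes, 11 of 14 tested members rose and 0 fell, the same counts adjusted over the list alone (adjusted p 4.37e-11), with a median log2 change of 3.24. SESA1 rose from 0.185 to 9 FPKM. In the light-harvesting and photosystem list, 18 of 40 members rose and 3 fell, or 19 and 3 adjusted over the list alone (adjusted p 6.10e-12 for the rises). RBCS1B, a Rubisco small subunit, rose by 0.99 and the photosystem I gene PSAD-1 by 0.88, while the light-harvesting genes LHCB1.4, LHCB1.1 (-1.29) and LHCB1.2 (-0.86) fell. Chlorophyll biosynthesis had 6 of 19 members higher and 0 lower, also when adjusted over the list alone (adjusted p 0.00163), among them the chelatase regulator GUN4 (0.84) and the reductase PORB (0.69).

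Auxin response and synthesis had 0 of 29 members higher and 5 lower in the dark, also when adjusted over the list alone (adjusted p 0.0015), such as SAUR10 (-0.96) and IAA5 (-0.68). Clock genes had 0 of 21 higher and 3 lower, again also when adjusted over the list alone (adjusted p 0.0317), with LHY at -0.74 and LNK2 at -0.73, while the list's median change was 0.09. The other 9 lists did not pass the test in either direction. They gave 2 higher and 0 lower of 11 for abscisic acid and cold stress (KIN1 1.23, RD29A 0.77), 1 and 2 of 11 for cell wall expansion (EXPA1 0.74, EXPA2 -1.08, XTH17 -0.65), 1 and 0 of 7 for flavonoid biosynthesis (F3H 1.5), and 1 and 0 of 7 for gibberellin and brassinosteroid (GA3OX1 0.59). Heat shock had 1 and 0 of 13 (HSP17.6A 1.5), light signalling 1 and 0 of 35 (RRC1 0.81), and splicing regulators 0 and 1 of 30 (U2AF65B -0.65). Jasmonate and defence had 0 of 5 called and root cell markers 0 of 15. Adjusted over the list alone, flavonoid biosynthesis had 4 higher and 1 lower, and these other 8 lists gave the same counts as above. Junction reads per library, listed for 29 of the genes raised in the dark and lowered by light in sfps-2, put sfps-2 dark replicate 2 below 0.5 of both other libraries in 17, such as MLO6 with 142, 13.2 and 250 reads, against 27.1, 38.6 and 36.6 in wild type. In genes raised by light, in contrast, dark replicate 2 was high in both genotypes. It was the highest library in 80 of 143 such genes in sfps-2 and in 83 of 143 in wild type, with ELIP2 at 88.7, 243 and 72.5 reads in sfps-2 and 37.3, 54.9 and 40.7 in wild type. The photosynthesis and chlorophyll calls in the dark come from groups that share this difference between replicates.

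After red light, the comparison asks how sfps-2 differs once the light response has begun. Seed storage genes were again higher in sfps-2, and some genes of the auxin response, of abscisic acid and cold stress and of the root cell markers were higher too, while 1 of 40 light-harvesting genes was called. SFPS was lower as given above. AIR1, an auxin-induced gene of roots, rose from 175 to 2570 FPKM (log2 change 3.87), SESA5 from 16.5 to 217 FPKM (3.71), and MES17, an esterase of methylated auxin, by 3.51. LCR85, a small cysteine-rich protein gene, rose by 5.42, the transcribed pseudogene AT3G29252 by 4.23 and AT4G12545 by 3.42. The largest falls were in AT5G40590 (-3.61), MRD1 (-3.49), AT3G21351 (-3.08), the peroxidase gene AT5G64120 (426 to 55.0 FPKM, -2.95), the thionin gene THI2.2 (-2.82) and the transcription factor gene MYB15 (-2.74).

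Of 20867 genes tested after red light, 685 were called higher in sfps-2 and 673 lower (50.4% higher). Seed storage and dormancy had 11 of 14 members higher and 0 lower, or 12 and 0 adjusted over the list alone (adjusted p 4.11e-13), with SESA4 at 2.77. Abscisic acid and cold stress had 5 of 12 higher and 0 lower (adjusted p 1.83e-04), with COR15A at 1.64 and KIN1 at 1.46. Auxin response and synthesis had 6 of 29 higher and 0 lower (adjusted p 0.00163), with GH3.3, an auxin-conjugating enzyme, at 2.57 and IAA5 at 1.66. Root cell markers, which stand for another tissue in whole seedlings, had 6 of 15 higher and 0 lower (adjusted p 4.44e-05), with PRP3 and PRP1 both at 2.01 and all 15 members' median at -0.04. These 3 lists had the same counts adjusted over the list alone.

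The other 10 lists did not pass after red light. Clock genes had 1 higher and 3 lower of 21 (ELF4 1.00, LHY -0.82, LNK2 -0.81), cell wall expansion 0 and 1 of 11 (XTH17 -0.88), chlorophyll biosynthesis 0 and 1 of 19 (DVR -0.63), and flavonoid biosynthesis 1 and 0 of 11 (FLS1 0.92). Heat shock had 1 and 0 of 13 (HSP17.6A 1.39), jasmonate and defence 0 and 1 of 5 (PR1 -1.28), light harvesting 1 and 0 of 40 (LHCB1.4 0.87), light signalling 1 and 0 of 35 (RRC1 0.69), and splicing regulators 1 and 0 of 30 (GRP7 0.70). Gibberellin and brassinosteroid had 0 of 7 called. Adjusted over the list alone, heat shock had 1 higher and 1 lower, and these other 9 lists gave the same counts.

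**Figure D2:**
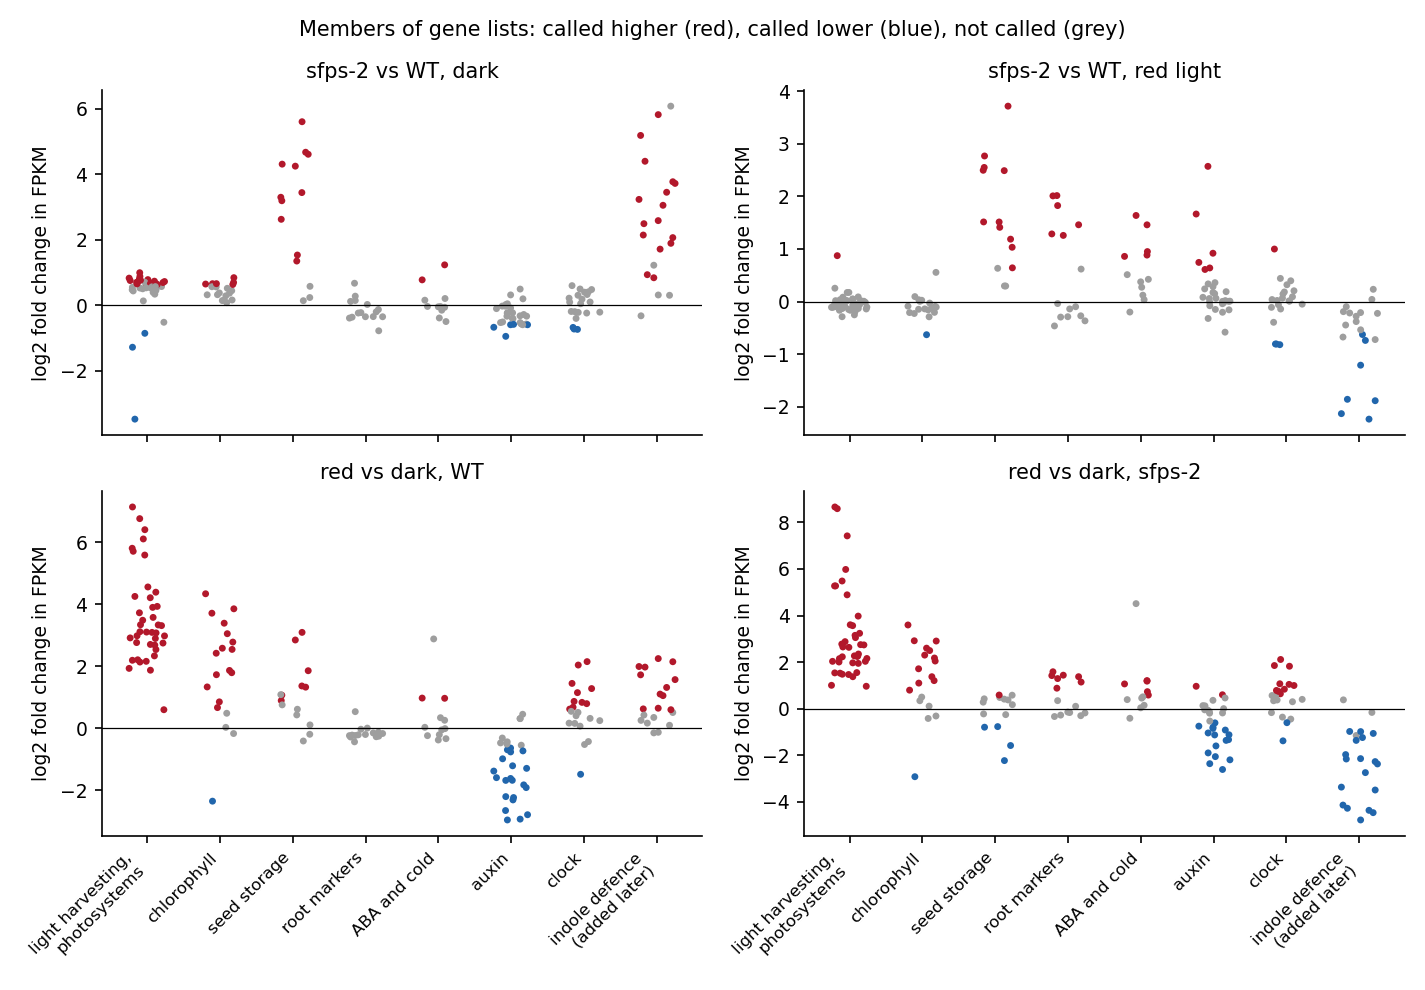
Log2 fold change in FPKM (y axis) of each tested member of 7 fixed gene lists and of 1 list added after the values were seen (x axis), in the 4 comparisons, with each y axis on its own scale and called members in red (higher) or blue (lower). In seed storage and dormancy 11 of 14 members, not all of them the same, were higher in each light condition, and light-harvesting and photosystem genes had 18 rises in the dark against 1 after red light.

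The genotype changes overlapped between dark and red light, comparisons that share no library. Of 20420 genes tested in both, 198 were higher in both against 32.6 under independence (odds ratio 10.1, Fisher's exact p 9.21e-103), SESA5 among them, and 133 were lower in both against 13.1 (odds ratio 18.0, p 7.21e-98), SFPS and MRD1 among them. A further 180 genes were higher in sfps-2 in the dark and lower after red light, against 33.7 (odds ratio 8.20, p 1.26e-82), such as PXMT1, CYP71A12 and GSTF6. The opposite pattern held for 9 genes against 12.7 (odds ratio 0.698, p 0.385).

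Red light in wild type asks which genes respond to 3 h of light when SFPS is present. All listed photosynthesis genes and most listed chlorophyll and flavonoid genes rose, and most listed auxin genes fell. LHCB1.1, a light-harvesting gene, went from 7.28 to 1027 FPKM (log2 change 7.14), RBCS1B rose by 6.76, LHCB1.2 by 6.41, the early light-induced genes ELIP1 and ELIP2 by 6.37 and 6.24, and LHCB2.2 by 6.11. PIL1, a shade-induced bHLH gene, went from 43.5 to 1.75 FPKM (-4.64), and the cell wall enzyme XTH15 from 1331 to 88.7 FPKM (-3.91). AT5G02540 (-4.07), the SAUR gene AT4G13790 (-3.96), CYP96A5 (-3.70) and RTFL21 (-3.68) fell as well.

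In wild type 3078 of 20635 genes tested were called higher and 1208 lower after red light. All 40 light-harvesting and photosystem genes rose (adjusted p 3.99e-32). In chlorophyll biosynthesis 15 of 19 rose and 1 fell (adjusted p 1.17e-08), with the chelatase subunit CHLH at 4.34, GUN4 at 3.86 and the reductase PORA at -2.35. In flavonoid biosynthesis 10 of 11 rose and 0 fell (adjusted p 5.74e-07), with CHS, chalcone synthase, at 5.31 and F3H at 5.29. Auxin genes had 0 of 29 higher and 21 lower (adjusted p 1.13e-18), with IAA29 at -2.95 and SAUR22 at -2.93. Clock genes had 10 of 21 higher and 1 lower (adjusted p 0.00198), with PRR9 at 2.15, LNK1 at 2.04 and BOA at -1.48. Light signalling had 14 of 35 higher (adjusted p 0.00161) and 10 lower (adjusted p 1.74e-04), with BBX25 at 5.49, PIF7 at 4.95 and ATHB2 at -3.30. The call for falls in light signalling ended with q alone as the criterion. Heat shock genes, listed as a sign of handling, had 9 of 13 higher and 0 lower, or 10 and 0 adjusted over the list alone (adjusted p 1.26e-04), with HSP70 at 2.18 and HSP90.1 at 1.5.

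Seed storage had 7 of 14 higher and 0 lower in wild type after light (adjusted p 0.00953), with SESA1 at 3.1 and SESA2 at 2.85. Cell wall expansion had 3 of 11 higher and 4 lower (adjusted p 0.0119 for the falls), with EXPA1 at 1.72, XTH22 at 1.22 and EXPA11 at -1.67. Gibberellin and brassinosteroid had 1 of 7 higher and 3 lower (adjusted p 0.0243 for the falls), with the catabolic gene GA2OX1 at 3.70, GA3OX1 at -0.77 and CPD at -0.80. Abscisic acid and cold stress (2 higher and 0 lower of 12, RD29A 0.98, KIN1 0.97), splicing regulators (1 and 1 of 30, SCL30A 0.61, GRP7 -0.59), jasmonate and defence (0 of 5) and root cell markers (0 of 15) did not pass. Except in heat shock, the counts for wild type were the same adjusted over the list alone.

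Red light in sfps-2 asks which of these responses persist without SFPS. All listed photosynthesis genes rose and 16 of 29 auxin genes fell here too, and a set of genes that had been high in dark sfps-2 fell. LHCB1.1 rose by 8.66, LHCB1.4 from 2.90 to 1112 FPKM (log2 change 8.59), LHCB1.2 by 7.42, LHCB2.2 by 5.98, the lipid transfer gene AT5G48490 by 5.55 and the thioredoxin gene CDSP32 by 5.55. PIL1 changed by -5.24, PXMT1 from 203 to 5.77 FPKM (-5.14), the germin-like gene GLP4 by -5.08, AT1G26380 by -4.83, CYP71A12 by -4.77 and the phospholipase gene PLA2A by -4.52. Of the genes that sfps-2 raised in the dark and light lowered in sfps-2, those with junction reads per library set sfps-2 dark replicate 2 apart, as given above.

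In sfps-2 2601 of 20970 genes tested were called higher and 1882 lower after red light. All 40 light-harvesting and photosystem genes rose (adjusted p 4.74e-35). Chlorophyll biosynthesis had 13 of 19 higher and 1 lower (adjusted p 2.61e-07; CHLH 3.59, PORC 2.92, PORA -2.92), and flavonoid biosynthesis 9 of 10 higher and 0 lower (adjusted p 6.21e-07; CHS 4.63, F3H 3.96). Auxin genes had 2 of 29 higher and 16 lower (adjusted p 5.83e-09 for the falls), with IAA5 at 0.96, SAUR22 at -2.61 and IAA29 at -2.36. Clock genes had 10 of 21 higher and 2 lower (adjusted p 5.69e-04), with LNK1 at 2.11, ELF4 at 1.85 and BOA at -1.38. Light signalling had 13 of 35 higher (adjusted p 0.00109) and 10 lower (adjusted p 0.00364), with PIF7 at 4.64, HYH at 3.11 and ATHB2 at -3.19. Root cell markers had 7 of 15 higher and 0 lower (adjusted p 0.00542), with PRP1 at 1.59. Abscisic acid and cold stress had 5 of 12 higher and 0 lower (adjusted p 0.0421), with LEA4-5 at 1.21 and KIN1 at 1.18, and this call ended when genes needed an FPKM of 1. Cell wall expansion had 3 of 11 higher and 4 lower (adjusted p 0.0476 for the falls), with XTH22 at 1.48, XTH15 at -3.89 and EXPA11 at -1.60, and this call ended under that same filter and with q alone.

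Seed storage (1 of 14 higher and 4 lower in sfps-2; SESA1 -2.23, SESA3 -1.58, EM6 0.59), heat shock (4 and 0 of 13; HSP70 1.72, HSFA2 1.51), gibberellin and brassinosteroid (1 and 2 of 7; GA2OX1 4.23, CPD -1.05), jasmonate and defence (0 and 1 of 5; JAZ1 -0.59) and splicing regulators (1 and 0 of 30; SCL30A 0.66) did not pass. Adjusted over the list alone, heat shock had 5 higher and jasmonate and defence 0 higher and 2 lower, and the other lists the same counts as above.

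The response to light was then compared between genotypes gene by gene. The difference in log2 change passed for 1215 of 20420 genes, 277 with a higher response in sfps-2 and 938 with a lower one. Differences between libraries bear on this comparison, since sfps-2 dark replicate 2 stood apart as given above, and sfps-2 red light replicate 3 had the smallest change in 111 of 169 light-raised genes with junction reads (median log2 change 1.43 against 1.81 and 1.75). PXMT1 rose by 2.05 in wild type and changed by -5.14 in sfps-2, a difference of -7.19. AT1G26380 differed by -7.57 and CYP71A12 by -7.02. In all, 199 genes were called in opposite directions, 175 of them up in wild type and down in sfps-2. The 3 smallest p belonged to the noncoding RNA genes AT3G01313 (-2.33), AT1G03935 (-1.56) and AT1G20015 (1.34), whose standard errors, computed from the authors' test statistics and rescaled to the p-values, were 0.00137 at most, against 0.162 for PXMT1 in wild type. The tables were normalized separately, and a group's median log2 FPKM differed between tables by 0.03 at most. The count fell to 297 genes when standard errors were used without rescaling to the p-values.

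Light-harvesting genes had 17 of 40 members with a different light response, 3 stronger and 14 weaker in sfps-2 (adjusted p 4.43e-10 over the 14 lists, Fisher's exact test). Seed storage had 8 of 14, 1 higher and 7 lower (adjusted p 2.34e-06), root cell markers 7 of 15, all higher in sfps-2 (5.10e-05), and abscisic acid and cold stress 4 of 12, all higher (0.0147). Auxin, with 5 of 29 higher, and chlorophyll biosynthesis, with 4 of 19 lower, both reached an adjusted p of 0.0622. Cell wall expansion had 1 of 11 called, flavonoid biosynthesis 1 of 10 and jasmonate and defence 1 of 5. Clock, light signalling, splicing regulators, heat shock, and gibberellin and brassinosteroid had 0 members called by this test. In the light-harvesting list, 18 of 40 members were called higher and 3 lower in dark sfps-2, and 1 and 0 after red light. All 40 rose with light in both genotypes. Over 4243 genes called in wild type, the slope of sfps-2 on wild type changes was 0.785 (95% bootstrap interval 0.767 to 0.804), and over 4355 genes called in sfps-2, the slope of wild type on sfps-2 was 0.669 (0.633 to 0.701). Selecting genes on 1 genotype lowers the slope in the other, and genes are not independent replicates.

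**Figure D3:**
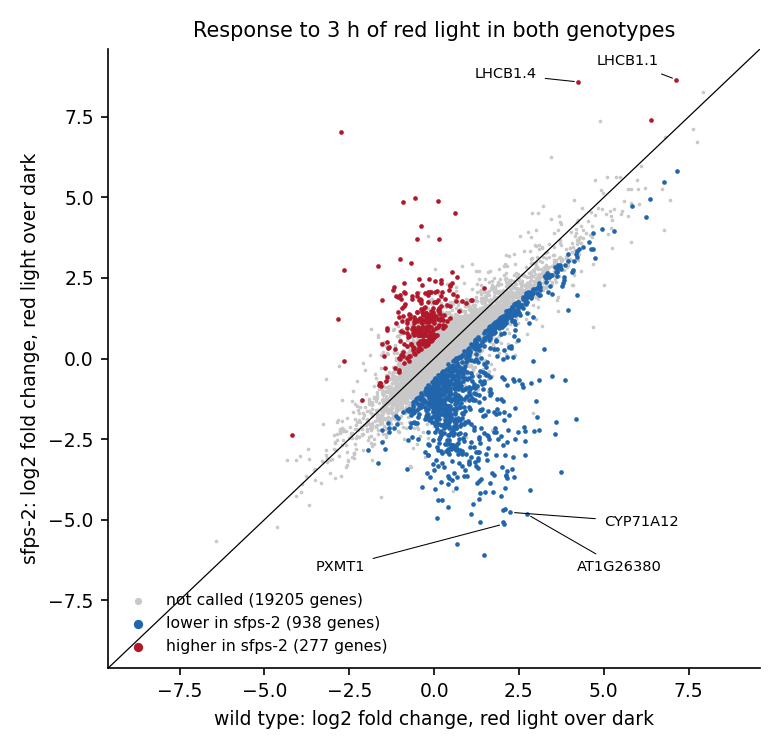
Log2 fold change from dark to red light in wild type (x axis) and sfps-2 (y axis) for 20420 genes, with the 277 genes whose response was higher in sfps-2 in red and the 938 lower in blue. PXMT1, CYP71A12 and AT1G26380 lie on the positive side for wild type and the negative side for sfps-2.

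Splicing was compared between genotypes first in the dark. The authors' lists, with FDR under 0.05 and a change of at least 3 points, held 972 events in 787 genes, 612 higher and 360 lower in sfps-2. SFPS intron 1 had the largest change, 94.9 points. This intron lies in the mutated gene itself. With 0 reads at its 3' boundary in sfps-2, as given above, the change does not show retention of the whole intron. Intron and exon numbers are those of the authors' bins, counted along the gene. Intron 7 of PCAP1, a plasma membrane cation-binding protein gene, had a retention of 82.3% ± 1.41 (SD, n = 3) in wild type and 21.8% ± 0.855 (SD, n = 3) in sfps-2. Retention of intron 7 of RIK, a KH-domain protein gene, went from 85.7% ± 2.65 to 25.2% ± 6.83 (SD, n = 3), and of intron 5 of CKB1, a casein kinase subunit, from 64.1% ± 2.43 to 9.94% ± 2.83 (SD, n = 3). Inclusion of exon 3 of AT2G31600 rose from 12.8% ± 8.68 to 75.9% ± 17.5 (SD, n = 3). For intron 1 of ATGLR1.2, listed at -68.1 points, a wild type dark library had 0 reads. The replicate ranges were apart for each of these events, which for 3 against 3 has a smallest two-sided exact p of 0.1, and a larger one for ATGLR1.2 with its 2 wild type libraries.

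Among light signalling genes 3 of 35 had an event in the dark (not enriched, adjusted p 0.667). The share of exon 15 of RRC1, a splicing factor gene of the phytochrome B pathway, rose from 72.0% ± 3.66 to 96.4% ± 0.0429, and its intron 15 fell from 12.9% ± 0.587 to 3.77% ± 0.689 (SD, n = 3). Retention of intron 2 rose in FHY1, a phytochrome A import factor, from 8.24% ± 0.565 to 13.9% ± 1.16, and in FHL from 5.99% ± 1.97 to 11.9% ± 2.69 (SD, n = 3). Clock genes with an event numbered 4 of 21 (adjusted p 0.0504). They were ELF3 intron 2, at 23.9% ± 2.76 and 37.7% ± 1.86, PRR7 intron 6, at 38.3% ± 4.37 and 24.4% ± 1.93, TOC1 intron 1, at 11.4% ± 0.208 and 18.5% ± 1.55, and RVE8 intron 9, at 13.7% ± 2.03 and 18.5% ± 1.55 (SD, n = 3). Splicing regulators had 7 of 30 with an event (adjusted p 0.00142 over 56 tests, Fisher's exact test), GRP7, RS2Z32, RS2Z33, RS40, SCL33, SR34B and SR45A, and 4 with changes of at least 10 points (adjusted p 0.0275). SR34B intron 12 went from 78.3% ± 3.31 to 51.9% ± 8.16, RS40 exon 5 from 25.4% ± 2.76 to 12.5% ± 0.609, SCL33 intron 5 from 68.1% ± 4.70 to 55.5% ± 3.54 and SR45A intron 5 from 29.3% ± 0.660 to 19.3% ± 3.08 (SD, n = 3). Auxin genes had 1 of 29, IAA14, and the other 10 lists 0. Genes were not matched for number of introns in the splicing list tests, so a preference for a list cannot be read from them.

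After red light the lists held 992 events in 827 genes, 682 higher and 310 lower in sfps-2. SFPS intron 1 again changed most, by 91.1 points. At alternative 3' splice sites, inclusion of the bin between a pair of sites rose in GSTZ1, a gene of tyrosine breakdown, from 6.50% ± 2.21 to 64.2% ± 2.78, in AT3G58450 from 37.4% ± 10.6 to 87.8% ± 4.22, in AT1G19330 from 27.9% ± 4.45 to 80.5% ± 2.50, and in HCF109, a gene for a plastid release factor, from 3.16% ± 1.19 to 55.0% ± 2.44 (SD, n = 3). RIK intron 7 went from 77.3% ± 5.73 to 24.7% ± 2.73 (SD, n = 3).

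Light signalling had 3 of 35 with an event after red light (adjusted p 0.673), FHY1, PIF3 and RRC1. RRC1 intron 15 fell from 16% ± 2.32 to 4.63% ± 0.749 and FHY1 intron 2 rose from 7.71% ± 1.04 to 12.6% ± 2.19 (SD, n = 3). Clock genes had 6 of 21 (adjusted p 0.00142, Fisher's exact test), CCA1, ELF3, LNK2, PRR7, RVE8 and TOC1, a call that ended with changes of at least 10 points (2 genes, adjusted p 0.361). PRR7 intron 4 went from 18% ± 3.24 to 32.3% ± 4.74, ELF3 intron 2 from 19.1% ± 2.36 to 30.1% ± 5.02, RVE8 intron 1 from 14.6% ± 2.21 to 24.3% ± 2.18 and TOC1 intron 1 from 9.27% ± 1.25 to 17.1% ± 2.69 (SD, n = 3). Splicing regulators had 7 of 30 (adjusted p 0.00142, Fisher's exact test), GRP7, PTB2, RS2Z33, RS40, SCL33, SR34B and U2AF65B, which also ended with 10 points (2 genes, adjusted p 0.570). SR34B intron 12 went from 85.1% ± 3.57 to 52.5% ± 9.39, PTB2 exon 9 from 13.4% ± 6.39 to 29.2% ± 2.31 and RS40 exon 5 from 20.6% ± 3.72 to 11.5% ± 0.238 (SD, n = 3). Root cell markers had 1 of 15, PRP3, and the other 10 lists 0.

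The dark and red light lists shared 412 events, 411 of them in the same direction, including SFPS, RIK, ELF3, TOC1 and SR34B. They shared 372 genes against 31 under independence (odds ratio 39.8, Fisher's exact test, p too small to be represented). The background genes were not matched for number of introns. A limma fit on the log2 odds of retention in 582 bins listed for all libraries found 0 bins with a genotype by light interaction, and 27 at an unadjusted p under 0.05. These bins are in both genotype lists or in both light lists, almost all with the same direction, which selects against an interaction, and events listed in 1 condition alone were not tested for it.

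Intron retention made up 904 of the dark events and 939 of the red light events. In the dark 62.9% of retained-intron events were higher in sfps-2 (95% Wilson interval 59.7 to 66.0, two-sided exact binomial p 6.56e-15), and after red light 68.7% (65.7 to 71.6, p 6.56e-31). Between dark and red light the shares had an odds ratio of 0.774 (Fisher's exact p 0.0106, adjusted p 0.0127), a test that counts the 412 shared events of any kind as if independent. Among events beyond the median size, with the median shift of introns chosen for their light response taken off, the shares were 57.4% and 57.9%, and among introns with a mean share of 20 to 80%, a choice made after the values were seen, they were 53.0% and 54.3%. Among introns with a share of 20 to 80% in wild type, most events fell, with 35.2% and 37.1% higher. Most events also fell in the light comparisons, with introns chosen on the dark share of each genotype. For changes of at least 10 points the dark share was 54.1% (p 0.161), which ends the call, and the red light share 59.1% (p 0.00151). Longer forms at alternative 3' splice sites were used more in sfps-2 in 21 of 27 events in the dark (adjusted p 0.0395, exact binomial test) and 21 of 28 after red light (adjusted p 0.0627). Alternative 5' splice sites were higher in 2 of 13 events in the dark (adjusted p 0.0898) and 2 of 6 after red light (adjusted p 0.855), and exon skipping events in 12 of 16 (adjusted p 0.219) and 9 of 11 (adjusted p 0.218).

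**Figure D4:**
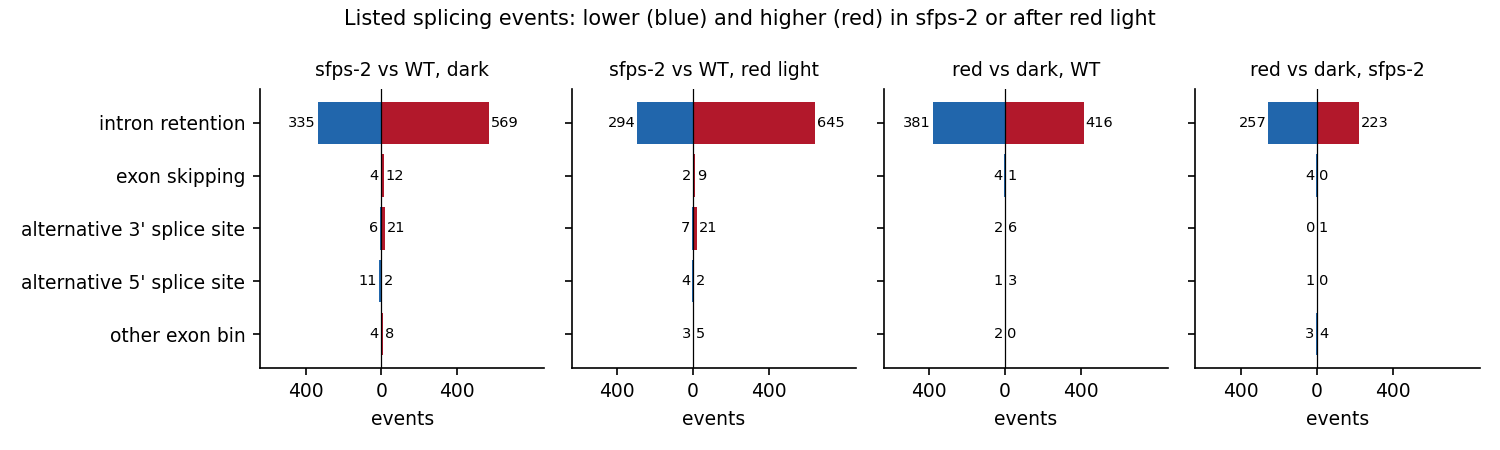
Number of listed splicing events (x axis) that were higher (red) or lower (blue) in each comparison by kind of event (y axis). Retained introns higher in sfps-2 numbered 569 of 904 in the dark and 645 of 939 after red light, against 416 of 797 for light in wild type.

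For red light the lists held 816 events in 610 genes in wild type (426 higher and 390 lower) and 493 events in 405 genes in sfps-2 (228 and 265). Libraries were made from total RNA, so transcripts not yet spliced were not told apart from retained introns. In wild type, retention of intron 1 of CaS, a chloroplast calcium sensor gene, fell from 58.6% ± 8.40 to 6.22% ± 0.452, of AT3G08660 intron 3 from 71.8% ± 10.9 to 15.4% ± 3.15, and of AT4G26790 intron 2 from 86.3% ± 11.9 to 27.0% ± 6.10 (SD, n = 3). PIF7 intron 1 went from 57.8% ± 16.2 to 5.84% ± 2.3 (SD, n = 3) on 5 to 21 reads per dark library, and ATGLR1.2 intron 1, listed at -61.3 points, rested on 0 to 12. AT2G34080 intron 1 rose from 6.16% ± 1.41 to 57.5% ± 8.35 (SD, n = 3). Light signalling had 2 of 35 (adjusted p 0.952), PIF7 and BBX25, whose intron 1 had 3 to 18 reads per dark library and overlapping ranges. Clock genes had 6 of 21 (adjusted p 6.29e-04, Fisher's exact test), CCA1, ELF3, LHY, LNK1, LNK2 and RVE8, with CCA1 intron 4 at 24.0% ± 2.71 and 11.9% ± 2.94, LNK2 intron 7 at 29.5% ± 0.885 and 18.5% ± 3.2 and LHY intron 12 at 12% ± 2.89 and 2.35% ± 0.902 (SD, n = 3). Splicing regulators had 7 of 30 (adjusted p 6.29e-04), PTB2, RS2Z32, SCL30A, SCL33, SR34A, U2AF65A and U2AF65B, with U2AF65B intron 4 at 68.8% ± 3.83 and 51.5% ± 5.90 and U2AF65A intron 2 at 62.4% ± 3.91 and 45.7% ± 6.98 (SD, n = 3). Chlorophyll biosynthesis had 5 of 19 (adjusted p 0.00161), CAO, CHLI1, CHLM, HEMC and PORC. With changes of at least 10 points, splicing regulators kept 4 genes (adjusted p 0.00941), while the calls ended for clock genes (2, adjusted p 0.265) and chlorophyll biosynthesis (1, adjusted p 0.916). Auxin had 2 of 29 (IAA14 and IAA29), light harvesting 1 of 40 (LHCB4.3) and the other 8 lists 0.

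In sfps-2, light lowered retention of intron 1 of COL2, a CONSTANS-like gene, from 59.7% ± 3.49 to 18.5% ± 7.74, of ASY3 intron 1 from 55.4% ± 10.3 to 3.67% ± 3.38, of AT5G57770 intron 1 from 52.0% ± 5.68 to 9.63% ± 4.77 (SD, n = 3) and of PRMT1A intron 2 from 59.3% ± 16.0 to 6.77% ± 3.12 (SD, n = 3), the last on 12 to 18 reads per dark library. MMH-1 exon 6 went from 94.9% ± 8.88 to 49.9% ± 12.4 (SD, n = 3). Clock genes had 3 of 21 with an event (CCA1, LHY and LNK2, adjusted p 0.0504), with LNK2 intron 7 at 30.4% ± 2.25 and 12.4% ± 3.28 and CCA1 intron 4 at 28.1% ± 4.58 and 18.8% ± 3.17 (SD, n = 3). Splicing regulators had 2 of 30 (adjusted p 0.572), SCL30A intron 3 at 32.1% ± 5.17 and 15% ± 2.29 and SR34A exon 3 at 28.8% ± 1.44 and 16.1% ± 0.447 (SD, n = 3). Light signalling had 3 of 35 (adjusted p 0.181), PIF7 on 2 to 15 dark reads, PHYD with overlapping ranges, and BBX25 intron 1, listed at -3.48 points on 1 to 5 dark reads, which turned to 1.67 without sfps-2 dark replicate 2 and to 5.08 without replicate 3. Chlorophyll biosynthesis had 2 of 19 (CHLI1 and CHLM), light harvesting 2 of 40 (LHCB2.3 and LHCB4.3) and the other 9 lists 0.

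Retained introns were higher after light in 52.2% of 797 events in wild type (exact binomial p 0.228) and 46.5% of 480 in sfps-2 (p 0.132). For changes of at least 10 points these shares were 48.9%, the other side of an even split, and 41.1% (p 0.025). Between dark sfps-2 against wild type and light in wild type the share had an odds ratio of 1.56 (Fisher's exact p 9.28e-06), although these comparisons share the dark wild type libraries and 52 events. The light lists shared 177 events, 170 in the same direction, and 175 genes against 11.8 under independence (odds ratio 35.4, Fisher's exact p 1.56e-164), with LNK2, LHY and CCA1 in both.

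Genes with a splicing event in sfps-2, such as RRC1 and LNK2, were called for expression in 8.88% of cases against 7.14% of other genes in the dark (odds ratio 1.27, Fisher's exact p 0.0765), and in 7.83% against 6.45% after red light (odds ratio 1.23, p 0.128). With changes of at least 10 points the odds ratios were 1.55 (p 0.0257) and 1.63 (p 0.0138). For the light response the odds ratios were 3.89 in wild type (p 9.20e-56) and 4.17 in sfps-2 (p 1.03e-42).

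Introns with changed retention in sfps-2 were longer than introns of expressed genes. Their 3' splice sites differed too, most clearly in introns retained less. This covers the 714 (dark) and 768 (red light) introns that matched an annotated intron, of 904 and 939 retention events. The median length was 197 bp (dark) and 172 bp (red light) for introns retained more and 142 bp and 161 bp for introns retained less, against 102 bp in expressed genes. Introns lowered by light had a median of 124 bp in both genotypes. The lengths of introns retained more and less were not tested against each other. First introns made up 30.5% of those retained more in the dark against 22% in expressed genes (adjusted p 8.73e-05, resampling) and 25.2% after red light (adjusted p 0.146), and introns raised by light held 32.2% in wild type and 34.6% in sfps-2. Introns retained less had, on average, 3' splice sites further from the consensus. Their mean log-odds score was lower by 1.95 (dark, 252 introns) and by 1.72 (red light, 225 introns) than in all introns of expressed genes, with differences of -1.59 and -1.35 against introns of the same genes. The two-sided resampling p was 1e-05 in each case, the smallest that 100000 random draws of introns give. Of 48 such tests 19 passed after adjustment, and 11 against introns of the same genes. At these sites C stood before the terminal AG in 45.6% (dark) and 49.3% (red light) against 65.2%, A in 19.0% and 21.8% against 6.54%, and G was the first exonic base in 28.6% and 28.0% against 51.5%. In introns retained more, C stood there in 73.2% (dark, adjusted p 0.00114, Fisher's exact test) and 69.2% (red light, adjusted p 0.125) against 65.1%. G was their first exonic base in 53.2% (adjusted p 0.611) and 57.6% (adjusted p 0.0159). Their mean 3' score was higher by 0.182 (adjusted p 0.284, resampling) and 0.340 (adjusted p 0.021). Against introns of the same genes neither difference in score passed (adjusted p 0.568 and 0.134).

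**Figure D5:**
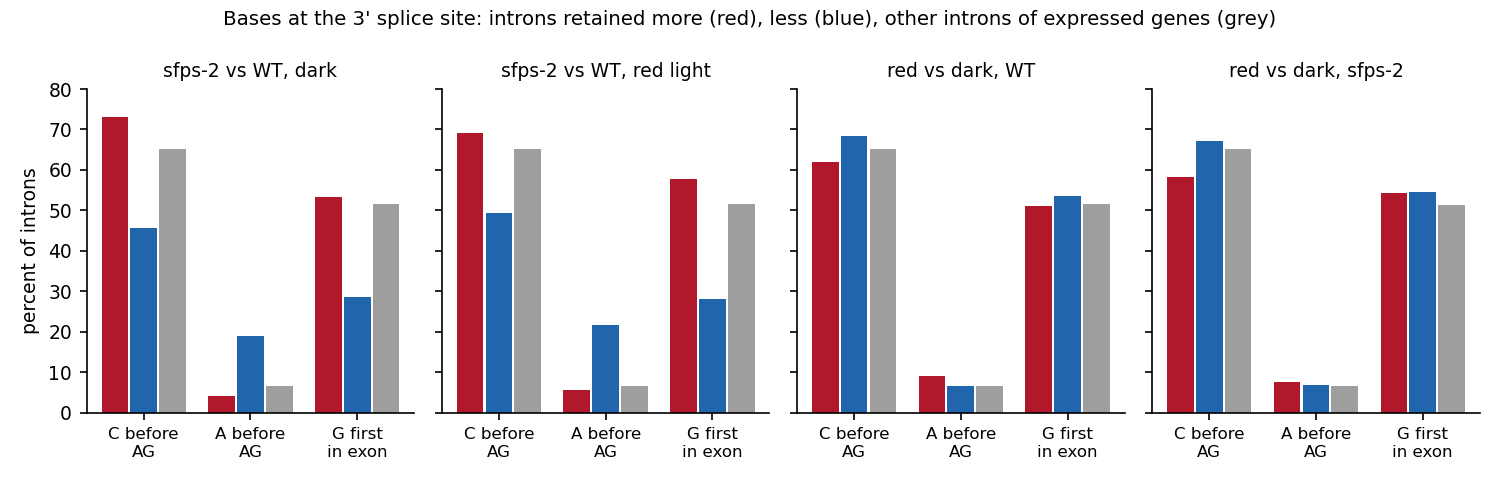
Share of introns (y axis, percent) with a given base at the 3' splice site (x axis), for introns retained more (red) or less (blue) in each comparison and other introns of expressed genes (grey). C before the AG was found in 45.6% of the introns retained less in the dark and 65.2% of other introns.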

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

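In this part, the tests of acceptor choice, of libraries standing apart, of scaling between tables and of other splits, and the test on introns with a mean share of 20 to 80%, were chosen after the results were seen. The response to red light differed between genotypes for 1215 genes by the test of the difference. The named genes with the smallest p differed by -2.33 (AT3G01313), -1.56 (AT1G03935), 1.34 (AT1G20015), -7.19 (PXMT1), -7.57 (AT1G26380) and -7.02 (CYP71A12) on the log2 scale. Among the lists, light harvesting had 17 members with a different response, seed storage 8, root cell markers 7 and abscisic acid and cold stress 4. The share of intron events that were higher in sfps-2 had an odds ratio of 0.774 between dark and red light by the test of the difference, which counts the 412 events shared by both lists as if independent, and the shares were nearly equal in both of the narrower sets of introns given below. The comparisons above do not use the authors' gene ontology tables, whose genes were pooled here per term over all of these tables. For 46 of 790 terms (5.82%) the pooled genes outnumber the background stated where the term was first read. Response to other organism, for example, had 111 genes against 96. Whether a single table exceeds its own background was not tested, and no enrichment from those tables is given here.

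Introns retained less in sfps-2 had 3' splice sites further from the consensus in both light conditions. Introns with a high starting retention could be weak to begin with, but against introns that lost retention with light in wild type, matched on the share in dark wild type, the score was still lower (difference -1.94, SE 0.241), by -2.41 (SE 0.412) and -2.84 (SE 0.406) in the low and middle strata of starting share, while the high stratum, with -0.801 (SE 0.424), lies within 2 SE of 0 and leaves this explanation open there. Competing annotated acceptors would leave introns with 1 annotated acceptor alike, yet these scored lower too, with a difference of -2.03 (SE 0.195) in the dark and -1.62 (SE 0.206) after red light. Where sfps-2 used the upstream of a pair of acceptors more, that acceptor scored lower relative to the downstream one than where the downstream site was used more (permutation p 0.0362 in the dark and 0.0205 after red light), although it was the lower of the pair in only 13 of 21 and 11 of 20 events, set against 6 and 7 events of the other kind. That acceptors of lower score are used more without SFPS thus stays a hypothesis resting on few events, found and tested on the same libraries.

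More introns rose than fell in sfps-2. Unspliced RNA raised in all introns of the sfps-2 libraries would be seen in introns chosen for their light response, whose log2 odds were shifted by 0.0231 in the dark and 0.106 after red light. With these shifts taken off, 57.4% of events beyond the median size rose in the dark (95% Wilson interval 52.8 to 61.8). After red light 57.9% rose (53.2 to 62.4). These shares cannot decide whether such a shift is the whole cause. Events had to change by at least 1.06 (dark) or 1.08 (red light) log2 odds, far more than the shifts, and were listed before any shift was removed. The 174 introns chosen for their light response were themselves higher in sfps-2 in 54.02% of cases in the dark and 57.47% after red light (exact binomial p 0.324 and 0.0577). A floor on falls from a low starting share cannot be told apart, because introns with 20 to 80% retention in wild type rose in 35.2% of events in the dark and 37.1% after red light, while the light comparisons gave 30.8% and 21.9% by the same choice of introns. With the mean of both groups between 20 and 80%, the shares were 53.0% (47.2 to 58.8) and 54.3% (48.0 to 60.4), so the excess may lie mainly in introns of low retention.

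In sfps-2, 478 genes were called higher in the dark than in wild type and lower after red light than in the dark, calls that share the sfps-2 dark libraries, so that some overlap arises without any effect and its size was not tested (median log2 changes of these chosen genes 1.41 and -1.70). Scaling between tables does not account for this, since a group's values differed between tables by a median log2 ratio of 0.0312 at most. Of 29 such genes with junction reads, sfps-2 dark replicate 2 lay below 0.5 of both others in 17, against 0 for replicate 1 and 1 for replicate 3, so the rise of these 17 may rest on the other libraries. None of the 16 indole defence genes among the 478 can be tested this way, as 0 of them have listed junctions, and for these a difference between libraries and an effect of genotype cannot be told apart. An effect of sfps-2 on dark stress responses remains open and was not tested.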

How the results depend on the processing

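Limma on listed events, leaving out events with a missing junction, fits without 1 library for retention shares, named events and the genotype by light bins, the replicate block for those bins, pseudocounts for named genes, the settings for intron features, and unscaled errors, scaling and tables in the comparison of light responses, and the pairing by reads per gene were chosen after the data were seen. Of the settings tried on the main results, 150 values kept their side or stayed within 1.5 times, 21 counts moved by more than 1.5 times, 8 results became stronger, 1 weaker and 1 reversed. For single genes and events 689 values kept their side, 7 became weaker and 2 reversed. Tighter thresholds gave fewer calls by construction. With a fold of 2, called genes numbered 730 (dark), 765 (red light), 2352 (light, wild type) and 2566 (light, sfps-2), and q alone gave 6858 for light in wild type. Changes of at least 10 points left 368, 353, 240 and 177 events, and FDR under 0.01 left 645, 618, 490 and 268. Splicing list tests fell from 6 to 2 with 10 points, which kept splicing regulators in the dark and for light in wild type and ended clock genes and splicing regulators after red light and clock and chlorophyll genes for light in wild type. Unscaled standard errors gave 297 genes for the light response, all 297 among the 1215, because the errors are wider. For the following changes the cause was not tested. The overlap of splicing and expression calls became stronger in the middle of 3 strata of FPKM in the dark (odds ratio 1.99), in the lowest stratum after red light (2.25) and with 10 points (1.55 and 1.63). The share of introns that rose was 54.1% in the dark with 10 points, 48.9% (reversed) for light in wild type and 41.1% for light in sfps-2.

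Limma passed 790 of 972, 823 of 992, 525 of 816 and 347 of 493 listed events. Without 1 library each these counts ranged from 666 to 690, 687 to 726, 330 to 453 and 202 to 268. The fit for light in wild type gave 330 without red light replicate 1, and that for light in sfps-2 gave 229 without dark replicate 1, 215 without red light replicate 1 and 202 without red light replicate 2. With a replicate block the counts were 695, 760, 429 and 277. In splicing shares, same-number libraries of different groups had a median r of 0.0154 over 18 pairs (-0.076 to 0.215), and 2 of 12 libraries went best with their own number throughout. In junction reads per gene, the same-number dark libraries of the genotypes went together (r 0.145 to 0.151), and those of the other comparisons did not all pass 0.1. The block moved no count by 1.5 times. No paired analysis was possible for expression because its tables hold no value per library, and leaving out libraries was not possible there for the same reason. The authors listed these events because they differ under the real grouping, so the limma counts are no independent test, and that 1 of 10 splits, the real one, had as many events in each comparison (highest other 0) was fixed by that choice. Also, 10 splits cannot give a share under 0.05. For genotype by light limma passed 0 bins (27 at an unadjusted p under 0.05), 0 to 1 without 1 library, with 1 bin without sfps-2 dark replicate 1, and 0 with a replicate block, while the highest of the other splits gave 1 and all 100 gave as many, as any split must against a count of 0, so nothing about chance follows. These bins were listed in both genotype or both light comparisons, which selects against an interaction, so the 0 does not show that light and genotype act independently.

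Without 1 library the share of introns that rose ranged from 61.9 to 63.4% (dark), 67.5 to 68.9% (red light), 50.7 to 53.7% (light, wild type) and 44.2 to 46.9% (light, sfps-2). It passed for wild type without dark replicate 3 (53.7%, exact p 0.0472) and for sfps-2 without red light replicate 2 (45%, 0.0373) and replicate 3 (44.2%, 0.0161). BBX25 intron 1 in sfps-2 light ranged from -28.7 to 5.08 points and reversed without dark replicate 2 (1.67) and replicate 3 (5.08), on 1 to 5 dark reads. Expression list tests kept 28 of 30 with q alone and 28 with an FPKM of 1.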

Other observations

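In this part, the indole list, the test on SFPS transcripts and all values per library were chosen after results were seen. Genes of indole defence metabolism, a list of 21 written after the values were seen, were called mostly in 1 direction per comparison. In dark sfps-2, 16 of 21 were higher than in wild type and 0 lower (median log2 change 2.49, Fisher's exact p 4.31e-17), among them PAD3, the last enzyme of camalexin synthesis, at 0.39 and 14.2 FPKM. After red light 0 of 20 were higher and 7 lower in sfps-2 (p 1.89e-06). Light raised 12 of 20 in wild type and lowered 0 (p 4.63e-06), and in sfps-2 it raised 0 of 21 and lowered 18 (p 1.35e-16). These p-values are not independent evidence, since the list was chosen on these samples. Whether the dark rise holds in each library is unknown, as 0 of the 16 have listed junctions, and sfps-2 dark replicate 2 stood apart in 17 of 29 other genes that rose in the dark and fell with light.

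In intron 1 of SFPS, sfps-2 had 34 reads at the 5' and 0 at the 3' boundary, against 57 and 34 in wild type (two-sided Fisher's exact p 2.81e-06, counting error only, with reads taken as independent). This p restates the reads that drew attention to the intron and is no separate test. Whether transcripts end inside the intron, or an insertion or deletion removes the 3' boundary, cannot be told apart from these reads.

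More retention may go with less mRNA. Genes whose introns rose in sfps-2 (479 in the dark, 548 after red light) had a lower median log2 change in FPKM than genes whose introns fell (277 and 252), by a difference of -0.0896 in the dark (permutation p 3.20e-04) and -0.0676 after red light (p 0.00419). The medians were -0.01 and 0.08 in the dark and -0.05 and 0.02 after red light, with SFPS left out.

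MRD1 and HEI10, whose loci overlap, were both lower in dark sfps-2. After red light MRD1 was called, and HEI10 stood at 4.91 and 0.809 FPKM with a q of 0.387 in the authors' deposited table. Some spliced junctions had 0 reads in a few libraries and many in all others. That of ARF3 (here locus AT2G24765) had 0 in 1 of 6 libraries and at least 499 in the others. That of the chloroplast gene ATCG00720 had 0 in 2 of 12 and at least 24369 in the others. That of ATBETAFRUCT4 had 0 in 3 of 12 and at least 246 in the others. These junctions belong to listed events, which the event counts above include. Listed changes were -4.46 points for ARF3 (genotype, red light) and 14.9 and 14.4 for ATCG00720 (genotype, dark and red light). For ATBETAFRUCT4 the change was -9.99 points (light, sfps-2). IRT1, an iron transporter gene of roots, had 2.09, 319 and 0 scaled reads in the sfps-2 dark libraries. It was called higher in dark sfps-2 than in wild type and lower after red light in sfps-2, although replicate 2 held nearly all of these reads.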
